A study of Mus musculus with 11 samples.

How the data were processed

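Granulocyte-macrophage progenitors from control mice (4 arrays), Irf8 knockout mice (3 arrays) and Irf8 knockout mice with an activated beta-catenin allele (4 arrays) were measured on Affymetrix mouse arrays of the perfect-match design, per the labels. Groups and replicate numbers were taken from the sample titles, and the design text says that the cells came from independent pools of mice. Every group carried the same poly(I:C) schedule, and the labels name no batch. The authors deposited 1 log2 value per probe set and array, for 45037 probe sets. The method of summarising and normalising them is not given in the sources used here. The log2 unit was read from the deposited values, which run from 0.988 to 13.2 with 0 missing values and 0 below 0. The values were used as deposited, without further normalisation. No column of the value table was left unused.

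The authors also deposited a signature of 638 genes with a p-value, a log2 fold change and a signed linear fold per gene, per the file headers. The test behind the deposited p-values is not named and limma p-values from the same arrays differ from them, so they were not used. The signed fold deposited by the authors equals the log2 fold change on the linear scale, to within 0.000498 in log2. The smallest fold in the table is 1.50 and its largest p-value 0.00160, so it holds genes past some limit on both. Whether a further rule of choice was used is not stated. The header does not name the groups compared. They were found from the values: each of the 638 log2 fold changes equals, to 3 decimals, the mean of the group with active beta-catenin minus the mean of control for at least 1 probe set. The same holds for 375 and 216 genes with the other pairs of groups, and of the 80 genes with an absolute log2 fold change of at least 1.5 for 80, against 4 and 1.

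No table that pairs probe sets with genes was used here. A gene of the signature was given the values of a probe set where exactly 1 probe set had its log2 fold change within 0.0005, which held for 197 genes, 133 higher and 64 lower. The other 441 matched 2 to 12 probe sets, and for these only the authors' own fold change is given. The join assumes that the authors' probe set is in the value table. For the 197 joined genes, values shifted by up to 0.05 would also have met a probe set in 42.6% of tries, and in 13.7% for the 63 joined genes with an absolute log2 fold change of at least 1.5, so a join would be wrong only where the authors' own probe set was missing. Joined genes lean to large changes, with a median absolute log2 fold change of 1.33 against 0.793 for the others. Symbols were updated through Entrez identifiers with a RefSeq gene table of assembly GRCm38.p6, in which 621 of the 638 were found and 54 symbols changed. No coordinates are given, since no genome build is named for the files.

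The design written before the data were examined counted genes, with 1 probe set per gene. Without names for most probe sets the unit became the probe set, and the rest of the design was kept. Probe sets above 2.73, the 25th percentile of all values, on at least 3 arrays were kept, which left 35423. All 11 arrays were fitted in 1 linear model with a mean per group (limma 3.58.1 in R 4.3.3, lmFit, contrasts.fit and eBayes), with 8 residual degrees of freedom. p-values were adjusted by Benjamini-Hochberg over probe sets within each of the 3 comparisons, and an adjusted p under 0.05 was a call. Fold changes are differences of group means of log2 values. Errors beside means are SDs over arrays, and those beside differences are limma standard errors. The model was tested on simulated arrays with the means and spreads of the real probe sets and known changes of 1.5-fold, 2-fold and 4-fold. The simulated values were independent and had the same spread in every group, so recovery on the real arrays may be lower. Recovery also depends on how many probe sets change, and 66 or 67 per fold size changed in each simulated comparison. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

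Of 31 gene lists written before the data were examined, 20 had a member in the signature. The direction of lists with at least 3 signature members was tested with Fisher's exact test against the rest of the signature. Lists with at least 3 members with values, which were 2, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. The named genes were fixed by rule: Irf8 and Ctnnb1; in each comparison the 8 largest rises and 8 largest falls among calls whose groups do not overlap; up to 4 members of each list described, or 1 where none was called; and the 5 called signature genes with the largest rise and fall between the groups with and without active beta-catenin. With names for 197 probe sets the rule was applied to these, and the last part named Oas3 alone. Ctnnb1 could not be reported.

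Comparisons that share control arrays were set beside 50 simulations of unchanged groups and beside splits of the control arrays 2 and 2. Alternatives listed before the data were examined were no filter, a filter at the 50th percentile, quantile normalisation, centring each array on its median, a fit of 2 groups only, eBayes with trend and robust, array quality weights, the replicate number as a block, each array left out, and a 2-fold limit. The weights gave 0.542 to control array 4 and 0.450 to array 2 of the group with active beta-catenin, against at least 0.685 for each other array. A fit without these 2 arrays, and one with a covariate for a division of the arrays seen in 8 probe sets, were added after seeing the data.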

Results

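Expression was measured on 11 Affymetrix mouse arrays of granulocyte-macrophage progenitors, the bone marrow cells that give rise to neutrophils and monocytes. The cells were sorted as lineage-negative, Sca-1-negative, c-Kit-positive cells with CD34 and high Fc gamma receptor. Irf8 is a transcription factor that directs such progenitors towards monocytes, and mice without it develop a disease resembling chronic myeloid leukaemia. The control group had 4 arrays, the Irf8 knockout group had 3, and the group with both Irf8 knockout and an activated beta-catenin allele had 4. Beta-catenin, the effector of canonical Wnt signalling, was activated by excising exon 3 of 1 Ctnnb1 allele, which removes the part of the protein that marks it for degradation. Every mouse, controls included, received 400 µg of poly(I:C), a double-stranded RNA mimic that induces interferon, on days 0, 3 and 5. Marrow was taken 10 to 14 days after the last dose, and under 20 ng of RNA per sample was amplified. Mice with activated beta-catenin and intact Irf8 were not analysed here. Each array gave 45037 probe set values on a log2 scale, with array medians from 3.92 to 4.09. Pearson's r across probe sets, which are not independent replicates, lay between 0.971 and 0.994 for pairs of arrays of the same group and between 0.964 and 0.990 for pairs of different groups. On the first principal component control array 4 lay at −6.85, nearer to the knockout arrays, at −1.07 to 19.9, than to control arrays 1, 2 and 3, at −59.8 to −44.4. On the second principal component control array 4 lay at −44.6 and array 2 of the group with active beta-catenin at −49.1, array 3 of that group lay at 48.4, and the other 8 arrays lay between −6.73 and 20.6. The number of arrays limits the precision of every value below.

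Gene names could be attached to 197 probe sets, all of them members of the authors' deposited table of a progression signature of 638 genes. Counts over the whole array are therefore counts of probe sets, and each named gene below was chosen by the study as a signature gene. The signature was chosen on these arrays, so its membership is not independent evidence of any direction, and a gene outside it is unnamed here rather than unchanged.

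The targeted gene was examined first. The Irf8 probe set stood at 9.46 ± 0.234 (SD, n = 4) in control cells, 8.46 ± 0.505 (SD, n = 3) in Irf8 knockout cells and 8.06 ± 0.515 (SD, n = 4) with active beta-catenin in addition. Each of the 7 knockout arrays lay below each of the 4 control arrays. The difference from control was −0.998 (SE 0.281, limma adjusted p = 0.104) in the knockout group, which missed the threshold, and −1.40 (SE 0.261, adjusted p = 0.00688) in the group with active beta-catenin. Without control array 4 and array 2 of the group with active beta-catenin, a choice made after seeing the data, the first difference was −1.08 (adjusted p = 0.0453), while without any 1 array its adjusted p lay between 0.0586 and 0.318. The position of this probe set relative to the deleted part of Irf8 was not given in the sources used here, so a remaining signal checks little. Ctnnb1 was not among the genes with a name here, and excision of an exon need not change its transcript level.

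**Figure D1:**
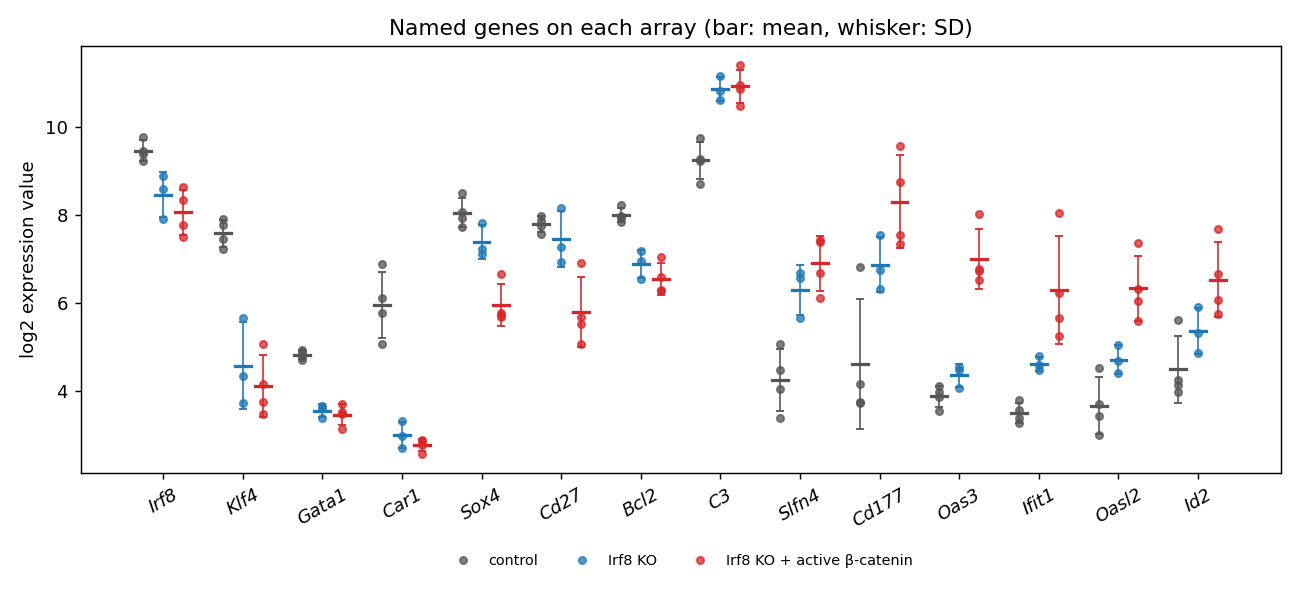
Log2 expression value (vertical axis) of 14 named genes (horizontal axis) in control (grey), Irf8 knockout (blue) and Irf8 knockout with active beta-catenin (red), 1 point per array, with the group mean as a bar and the SD as a whisker. Klf4, Gata1 and Car1 lie about as low in Irf8 knockout arrays as in those with active beta-catenin, whereas Oas3 has a mean of 4.36 in the knockout group against 7.01 with active beta-catenin.

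The comparison of Irf8 knockout with control asks what loss of Irf8 does to these progenitors. The 2 genes with values of the 20 in the erythroid list, and the monocyte regulator Klf4, were lower in knockout cells. These genes have values because the study chose them for a change against these same control arrays. They do not stand for the rest of their lists. Klf4, a transcription factor needed for monocyte formation, fell 8.07-fold, from 7.59 ± 0.308 (SD, n = 4) to 4.58 ± 0.992 (SD, n = 3). Car1, a carbonic anhydrase of red cell precursors, fell 7.75-fold, from 5.96 ± 0.755 to 3.01 ± 0.303. Gata1, the main transcription factor of erythroid and megakaryocyte cells, fell 2.42-fold, from 4.83 ± 0.0980 to 3.55 ± 0.146. C3, the central complement component, rose 3.06-fold, from 9.24 ± 0.429 to 10.9 ± 0.275, and Slfn4, a schlafen gene of myeloid cells, rose 4.15-fold, from 4.25 ± 0.707 to 6.30 ± 0.567.

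Over all 35423 probe sets tested, limma called 372 higher and 435 lower in Irf8 knockout at an adjusted p under 0.05, and 5072 had an unadjusted p under 0.05. Of the 807 calls, 805 had groups whose arrays did not overlap, a property that 15.6% of all probe sets showed and that chance gives to 5.71%. Of the 371 called higher without overlap, 29 carried a name, and Slfn4 was the highest of these at rank 23. Of the 434 called lower without overlap, 18 carried a name, and Klf4 was at rank 15. The changes that ranked above them belong to probe sets unnamed here. The largest of these differed by 6.16 (SE 0.410) among the rises and by −6.42 (SE 0.116) among the falls. Fbp1, a gluconeogenic phosphatase, rose by 1.41 (SE 0.280), and Hsd11b1, which regenerates active glucocorticoid, by 1.40 (SE 0.317). Hfe, a regulator of iron uptake, rose by 1.36 (SE 0.279), Mgst2, a microsomal glutathione transferase, by 1.28 (SE 0.272), the inflammatory caspase gene Casp4 by 1.25 (SE 0.252), and Gpc1, a cell-surface proteoglycan, by 1.21 (SE 0.151), with control array 4 nearest to the knockout arrays at 8.30. Adjusted p-values of these 6 genes lay between 0.00123 for Gpc1 and 0.0402 for Hsd11b1. Prdx4, a peroxiredoxin of the endoplasmic reticulum, differed by −1.45 (SE 0.272, adjusted p = 0.0159), Ifi209, a member of an interferon-inducible family, by −1.45 (SE 0.334, adjusted p = 0.0454), and Mfsd2b, an exporter of sphingosine phosphate in red cells and platelets, by −1.28 (SE 0.262, adjusted p = 0.0249). Klf4, Car1, Gata1, C3 and Gpc1 kept their calls without any 1 array. Without knockout array 1 the adjusted p was 0.119 for Slfn4, 0.115 for Fbp1, 0.194 for Hsd11b1, 0.153 for Mgst2, 0.126 for Casp4, 0.0913 for Prdx4 and 0.113 for Mfsd2b, and without knockout array 2 it was 0.0998 for Hfe and 0.181 for Ifi209. Leaving out control array 1, 2 or 3 also ended calls among these genes, except that of Prdx4. The calls of Hfe, Mgst2 and Hsd11b1 ended without any 1 of the 3 knockout arrays. That of Ifi209 ended in 9 of 11 such fits and was kept only without array 2 or 3 of the group with active beta-catenin. A predicted gene and a gene with only a locus number were skipped among the 8 named falls.

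Among the gene lists fixed from textbook knowledge, the members with values here behaved as follows in this comparison. In the erythroid list both such members, Gata1 and Car1, fell. In the monocyte list Klf4 fell, and Cd14, the co-receptor for bacterial lipopolysaccharide, was at 5.82 ± 0.548 (SD, n = 3) against 4.95 ± 0.666 (SD, n = 4), which did not pass (adjusted p = 0.401). Klf4 was also the 1 member with values of the list of genes that Irf8 activates. Bcl2, a survival gene listed among those that Irf8 represses, fell by 1.10 on the log2 scale (adjusted p = 0.0138), from 7.998 ± 0.164 (SD, n = 4) to 6.90 ± 0.318 (SD, n = 3), opposite to the direction the list names, and was not called without knockout array 2 (adjusted p = 0.0674) or 1. None of the 7 interferon-stimulated genes with values passed on its own over all probe sets tested, and 1 of 7 did when adjusted over the list alone. Without array 4 of the group with active beta-catenin, which enters only the estimate of spread, Ifit1 and Ddx58 passed (adjusted p = 0.0225 and 0.00643). The list's median difference was 0.71, with limma's camera at an adjusted p of 0.000690, which was lost with an estimated correlation (adjusted p = 0.320). Members of every list have values because the study chose them for a change against these same control arrays. Their direction and the p-values of lists are therefore not independent evidence here. None of the 4 stem cell genes with values passed over all probe sets tested, 3 of 4 did when adjusted over the list alone, and the list did not (camera adjusted p = 0.306). Tal1 passed without that same array (adjusted p = 0.0203) and Prom1 without control array 4 (adjusted p = 0.0184). The single members with values of the Wnt target and dendritic cell lists and both of the secondary granule list were not called over all probe sets tested. Adjusted over the list alone, 1 of the 2 granule genes passed. The calls rested on few arrays. Without control array 1, 2 or 3 the counts were 174 higher and 260 lower, 196 and 261, or 195 and 288. Without knockout array 1 or 2 they were 131 and 214, or 206 and 239, whereas without control array 4 they were 581 and 478. Array weights gave 995 and 921, and leaving out both control array 4 and array 2 of the group with active beta-catenin gave 832 and 769. In simulated arrays of this comparison, with independent values, 67, 67 and 66 of 35423 probe sets changed 1.5-fold, 2-fold and 4-fold. Of these, 16.4%, 71.6% and 98.5% were recovered in the same order.

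The comparison of cells with both lesions against control shows the joint state that the series title relates to blast crisis, the acute stage of the disease. Among genes with values, which the study chose in this comparison, interferon-stimulated genes and the neutrophil genes Cd177 and Il1r2 were higher. Of the stem cell genes with values 3 of 4 were lower, as were Klf4 and the erythroid genes Gata1 and Car1. Cd177, a surface glycoprotein of neutrophils, rose 12.9-fold, from 4.62 ± 1.48 (SD, n = 4) to 8.31 ± 1.05 (SD, n = 4), with control array 4 at 6.82 and a log2 difference of 3.69, or 4.42 without that array. Oas3, an antiviral oligoadenylate synthetase, rose 8.75-fold, from 3.88 ± 0.239 to 7.01 ± 0.683, with array 4 of the group with both lesions highest at 8.02. Klf4 fell 11.1-fold to 4.12 ± 0.697, and Sox4, a transcription factor of progenitors, fell 4.28-fold, from 8.06 ± 0.327 to 5.96 ± 0.471, with array 2 of that group highest at 6.66.

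limma called 1591 probe sets higher and 1273 lower in this comparison, and 7991 had an unadjusted p under 0.05. Of the 2864 calls, 2618 had groups that did not overlap, which chance gives to 2.86% of probe sets and which 14.1% of all probe sets showed. Of the 1469 called higher without overlap 130 carried a name, and of the 1149 called lower 57 did. Among the rises, Ifit1, which binds viral RNA, differed by 2.79 (SE 0.453, adjusted p = 0.00313) and Oasl2, a relative of Oas3, by 2.67 (SE 0.371, adjusted p = 0.00124). The decoy interleukin-1 receptor Il1r2 differed by 2.68 (SE 0.653, adjusted p = 0.0272), with 4.87 ± 1.78 (SD, n = 4) in the group with both lesions against 2.19 ± 0.0980, and its adjusted p was 0.0737 without control array 1 and over 0.05 without control array 2 or 3 or array 4 of the group with both lesions. The control mean of Il1r2 lay below the filter level of 2.73, so the size of its rise is uncertain. Slfn4 differed by 2.66 (SE 0.380), Wfdc21, a whey acidic protein family gene, by 2.56 (SE 0.533), and the uncharacterised transcript AB124611 by 2.15 (adjusted p = 0.00127). Among the falls, Car1 differed by −3.19 (SE 0.297) and Tns1, a tensin that links integrins to actin, by −2.57 (SE 0.318). Ifi209 differed by −2.05 (SE 0.309), Cd27, a tumour necrosis factor receptor family member of early progenitors and lymphocytes, by −1.99 (SE 0.350, adjusted p = 0.00507), and Ppic, a cyclophilin, by −1.98 (SE 0.304). A RIKEN transcript among the 8 largest named falls was skipped. Unnamed probe sets had the largest changes here as well, the largest of them 5.56 (SE 0.379) and −6.40 (SE 0.107).

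Gene groups are given by their members in the signature, with the authors' deposited table for those that have no values here. Of the interferon-stimulated list, 8 of 39 genes were in the signature, 7 of them higher. All 7 with values rose, whether adjusted over all probe sets or over the list alone, among them Oas2 by 1.98 (SE 0.357) and Ddx58, a sensor of viral RNA, by 1.59 (SE 0.243), with array 4 of the group with both lesions at 7.44. The eighth, Gbp3, was at −0.74 in the authors' deposited table. The stem cell list had 6 of 32 genes in the signature, 5 of them lower. Sox4, Cd27 and Tal1 fell, the last by 1.70 on the log2 scale (SE 0.275, adjusted p = 0.00310), and Prom1, a surface marker of stem and progenitor cells, rose by 1.34 (SE 0.347, adjusted p = 0.0355). Control array 3 was lowest of the controls for Tal1, at 5.19. Prom1 stood at 9.15 on array 4 of the group with both lesions and was not called without control array 1 or 3, knockout array 2 or any 1 array of that group (adjusted p up to 0.106). Hoxa9, a homeobox transcription factor, stood at −1.51 in the authors' deposited table. Both lists passed camera, at adjusted p = 1.02e-10 for the interferon list and 0.00323 for the stem cell list, and both held with an estimated correlation (adjusted p = 0.0368 for each), on members that the study had chosen in this same comparison.

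The erythroid list had 3 of 20 genes in the signature, all lower: Gata1 and Car1 fell, by 1.36 (SE 0.129) and 3.19 on the log2 scale, and the globin gene Hbb-b2 was at −1.20 in the authors' deposited table. The secondary granule and neutrophil list had 3 of 30, all higher: Cd177 and Il1r2 rose, and Anxa1, an anti-inflammatory annexin, was at 1.02 in the authors' deposited table. The primary granule and granulocyte progenitor list had 4 of 20, all higher in the authors' deposited table, with Csf3r, the receptor for granulocyte colony-stimulating factor, at 0.73, Serpinb1a, an inhibitor of neutrophil elastase, at 1.36, and Trem3 at 1.48. The monocyte list had 4 of 30, of which Cd14 rose by 1.63 (SE 0.404, adjusted p = 0.0293, and 0.0808 without control array 3, with its call also lost without control array 2 or array 4 of the group with both lesions) and Klf4 fell, while Adgre1, the macrophage marker F4/80, was at 1.30 and Ctsc at −1.24 in the authors' deposited table. Of the Wnt and beta-catenin target list 4 of 30 were in the signature. Rnf43, a ubiquitin ligase that removes Wnt receptors, was at 5.00 ± 0.796 (SD, n = 4) against 3.77 ± 0.286 (SD, n = 4) and missed the threshold (adjusted p = 0.0501). Its adjusted p lay between 0.0185 and 0.148 with single arrays left out, and passed without knockout array 2 or array 3 of the group with both lesions. The transcription factor gene Ascl2 stood at 1.46, the Wnt receptor gene Fzd7 at 0.70 and Bambi at −0.70 in the authors' deposited table. Of the Wnt pathway list, 1 of 32, Ctnnbip1, was in the signature, at 0.61 in the authors' deposited table. Of the dendritic cell list 3 of 25 were: Id2, an inhibitor of helix-loop-helix factors, rose by 2.04 (SE 0.437, adjusted p = 0.0144), with control array 4 at 5.62 and the call lost without control array 3 (adjusted p = 0.0505) or 1, while Bcl11a was at 0.73 and Tcf4 at −0.61 in the authors' deposited table.

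Smaller groups had fewer members. Both signature members of the class II antigen presentation list, H2-DMb2 and H2-Ob, were lower in the authors' deposited table, at −0.94 and −0.83, and so were both of the mast cell and basophil list, Mcpt8 at −1.60 and Hdc at −0.75. Bcl2, the 1 member of the list of genes repressed by Irf8 and of the apoptosis list, fell by 1.45 on the log2 scale (SE 0.186, adjusted p = 0.000732). The list of genes that Irf8 activates had 2, Klf4, which fell, and Ets2, at 0.86 in the authors' deposited table. In the authors' deposited table Bcl6 stood at 1.15 and Ccnd2 at −0.64 in the list of cytokine targets, Eno1 at 0.64 in glycolysis, Rab27b at −1.03 in megakaryocytes, Cd72 at −0.89 in B cells, and Thy1 at −1.08 in T and natural killer cells. The remaining 11 of the 31 lists had no gene in the signature: cell cycle, cell cycle inhibitors, ribosome biogenesis, oxidative phosphorylation, unfolded protein response, immediate early genes, inflammatory NF-kappa-B targets, feedback of mitogen-activated kinases, adhesion and homing, stroma, and sex-linked genes. Within the signature, 394 genes were higher and 244 lower, and a two-sided Fisher's exact test of direction against the other signature genes passed for none of the 8 lists with 3 or more members. The smallest adjusted p was 0.222, for the stem cell and erythroid lists. Among the array counts, those without control array 1, 2 or 3 were 804 higher and 735 lower, 888 and 763, or 893 and 763. Array weights gave 2532 and 2223. In simulated arrays of this comparison, with independent values, 67, 67 and 66 of 35423 probe sets changed 1.5-fold, 2-fold and 4-fold. Of these, 19.4%, 82.1% and 98.5% were recovered in the same order.

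The signature genes were then followed in the comparison of Irf8 knockout with control. Each of the 197 genes with values lay on the same side of control in Irf8 knockout cells as in cells with active beta-catenin, and 196 did without control array 1. In the 133 genes higher in the signature the median difference was 0.76 in Irf8 knockout against 1.29 with active beta-catenin, and in the 64 lower genes it was −0.87 against −1.40. The median ratio of the knockout change to the change with both lesions was 0.633, with quartiles of 0.475 and 0.761. These genes were chosen on the change with both lesions, and both changes share the control arrays. The signature runs from −3.47 to 3.69 in that change, yet unnamed probe sets outside it changed by −6.40 and 5.56. A further rule of choice, not named in the sources used here, may therefore shape the ratio. With separate control arrays for each change the median ratio of the 197 genes lay between 0.446 and 0.781 over 6 splits. Over the whole array the median ratio was 0.699 among the calls with both lesions and 0.973 among the 807 calls of Irf8 knockout. The former were chosen on the change that the ratio divides by, which can lower the median. The latter were chosen on the knockout change, which can raise it. The control arrays are shared here too, so these medians do not show how complete the change was in Irf8 knockout. Genes with a high ratio included Gata1 (0.936), Car1 (0.927) and C3 (0.961), whereas Oas3 (0.153) had little of the change in Irf8 knockout alone. Car1 stood at 3.01 in Irf8 knockout and 2.78 with both lesions, near the filter level of 2.73, and Gata1 at 3.55 in Irf8 knockout. Such low signal leaves little room for a further fall, so the ratios of Car1 and Gata1 do not show that the change was complete.

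limma called 48 of the 197 in Irf8 knockout against control, 30 higher and 18 lower and none against the direction of the signature, and 149 did not pass. Adjusted over the list alone, which is not independent evidence here, 148 passed. Of the other 35226 probe sets 2.15% were called, against 24.4% of the signature genes, which were chosen with the same control arrays, so the difference is not independent evidence. Against control, 196 of 197 passed with active beta-catenin, the exception being Rnf43. The 48 calls became 87 without control array 4, 21, 24 and 24 without control arrays 1, 2 and 3, and 14 and 21 without knockout arrays 1 and 2. They were 120 with array weights, and 109 without both control array 4 and array 2 of the group with active beta-catenin.

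**Figure D2:**
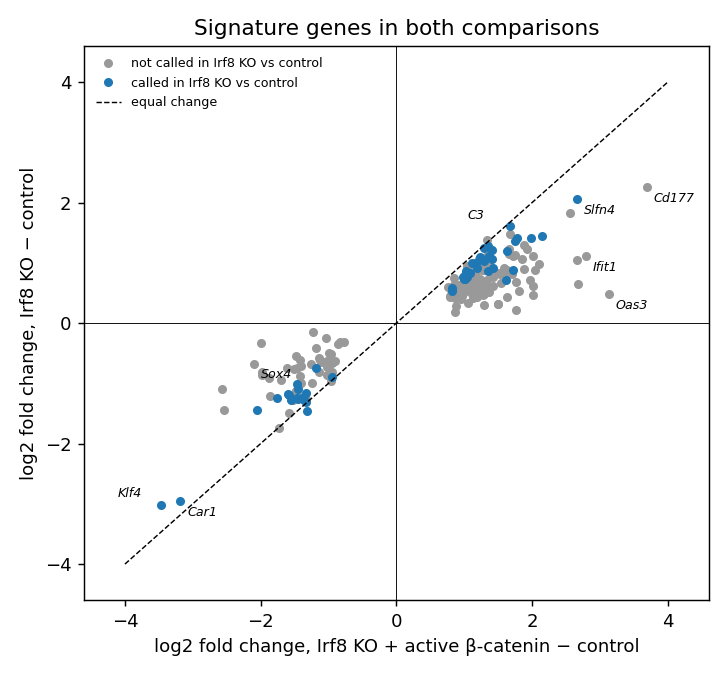
Log2 fold change of Irf8 knockout against control (vertical axis) plotted on that of Irf8 knockout with active beta-catenin against control (horizontal axis) for the 197 signature genes with values, which the study chose on the latter change, 1 point per gene, blue where limma called the gene in Irf8 knockout against control. All points lie in the quadrants of equal sign, and 194 of them lie closer to 0 on the vertical axis than the dashed line of equal change.

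Over the whole array, 338 probe sets were called higher and 392 lower in both comparisons against control, and 1 was called in opposite directions. Independent lists of the same sizes would share 16.7 and 15.6. Pearson's r of the fold changes across probe sets was 0.812, against a mean of 0.464 in 50 simulated sets of unchanged groups that shared the control arrays, which gave 0.00 shared calls on average. The simulated values were independent between probe sets. They lack deviations common to many probe sets of an array, which can move r and shared calls further from these means. The covariance was 0.109 against 0.0198 in the simulations, a difference of 0.0892. When each comparison was given its own 2 control arrays, r lay between 0.505 and 0.723 and 248 to 363 calls were shared over 6 such splits. Of the 807 calls of Irf8 knockout against control, 90.5% were called in the same direction with active beta-catenin, while 2133 calls of the latter were not called in Irf8 knockout alone, a comparison with fewer arrays. Of all 2864 calls with active beta-catenin, 2821 had the same sign in Irf8 knockout.

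The comparison of Irf8 knockout with and without active beta-catenin asks what the second lesion adds. Oas3 was the 1 probe set called higher. It stood at 7.01 ± 0.683 (SD, n = 4) with active beta-catenin against 4.36 ± 0.260 (SD, n = 3) in Irf8 knockout alone, a 6.28-fold rise (log2 difference 2.65, SE 0.301, limma adjusted p = 0.0254). The 1 probe set called lower is unnamed here and stood at 5.34 ± 0.136 against 6.88 ± 0.220 (log2 difference −1.54, SE 0.138, adjusted p = 0.00385), with control cells at 6.03 ± 0.166. Irf8 itself differed by −0.40 (SE 0.281, adjusted p = 0.789). Rnf43, the 1 member with values of the Wnt and beta-catenin target list, was not called, over all probe sets tested or over the list alone. With Ctnnb1 unnamed as well, no transcript here checks the activated allele in this comparison.

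Of the 35423 probe sets, 2590 had an unadjusted p under 0.05 in this comparison, and 7% had groups that did not overlap, against 5.71% by chance. Oas3 was not called, and the count of rises was 0, without knockout array 1, 2 or 3 (adjusted p = 0.141, 0.167 and 0.148) or array 1 or 3 of the group with active beta-catenin (adjusted p = 0.0831 and 0.0659). Oas3 was not called without control array 2, 3 or 4 either (adjusted p = 0.0769, 0.0752 and 0.0510), which enter the estimate of spread, and a limma fit of these 2 groups alone called 0 higher and 0 lower. Without array 2 of that group there were 1 higher and 10 lower, and 4 signature genes were called rather than 1. In simulated arrays of this comparison, with independent values, 67, 67 and 66 of 35423 probe sets changed 1.5-fold, 2-fold and 4-fold. Of these, 20.9%, 80.6% and 98.5% were recovered in the same order. The simulated groups had equal spread and no deviations common to many probe sets, so these shares may overstate recovery on the real arrays. The small number of calls therefore does not show that few changes of 2-fold or more exist.

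All 7 interferon-stimulated genes with values were higher with active beta-catenin, with a median difference of 1.26. Oas3 passed over all probe sets tested, and all 7 passed when adjusted over the list alone. The values of Oasl2 were 6.33 ± 0.746 (SD, n = 4) against 4.72 ± 0.328 (SD, n = 3), those of Dhx58, a helicase that regulates RNA sensing, 6.17 ± 0.466 against 5.00 ± 0.389, and those of Ifit1 6.30 ± 1.23 against 4.62 ± 0.163. The list passed camera (adjusted p = 2.61e-12), and this held with an estimated correlation (adjusted p = 0.0154). The mean of the 7 genes was 6.63 ± 0.723 (SD, n = 4) with active beta-catenin, 5.21 ± 0.226 (SD, n = 3) in Irf8 knockout and 4.46 ± 0.221 (SD, n = 4) in control, and the arrays of the 3 groups did not overlap. These genes have values because the study chose them for a change between active beta-catenin and control on these arrays, so no test of this mean is given and the list's p is not independent evidence.

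The 4 stem cell genes with values had a median difference of −1.09, with Prom1 near 0. None passed over all probe sets tested, and 3 passed when adjusted over the list alone. Sox4 stood at 5.96 ± 0.471 (SD, n = 4) against 7.38 ± 0.384 (SD, n = 3) in Irf8 knockout and Cd27 at 5.80 ± 0.792 against 7.46 ± 0.637, with adjusted p = 0.266 and 0.411 over all probe sets. The list passed camera (adjusted p = 2.22e-05) and held with an estimated correlation (adjusted p = 0.0139). These members too were chosen by the study on these arrays of active beta-catenin, so the p is not independent evidence, and the effect of that choice was not tested for this list. Prom1 differed by −0.04 (adjusted p = 0.987), and by 0.15 and 0.01 without knockout array 1 or 2. Without array 2 of the group with active beta-catenin Sox4 and Cd27 passed (adjusted p = 0.0316 and 0.0390). Of the 197 signature genes, 194 had the sign of the signature in this comparison, 1 passed over all probe sets tested and 42 passed adjusted over the list alone.

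**Figure D3:**
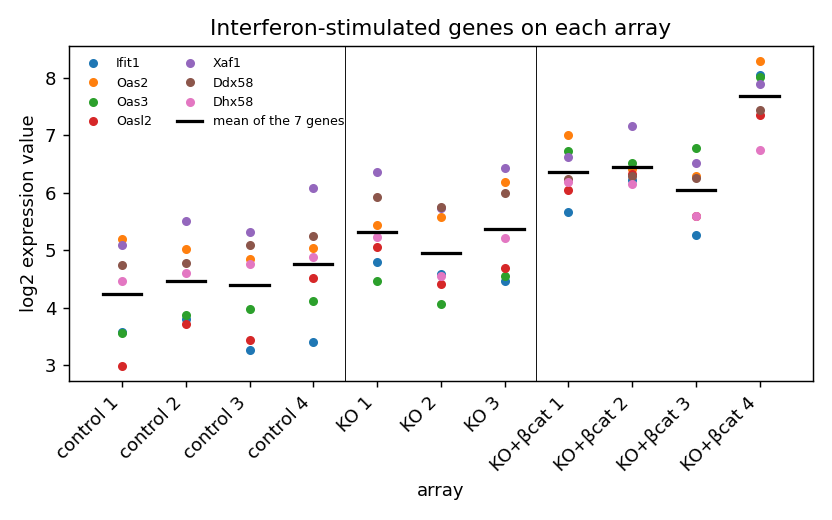
Log2 expression values (vertical axis) of 7 interferon-stimulated genes on each of the 11 arrays (horizontal axis, with vertical lines between the 3 groups), 1 coloured point per gene and a black bar for their mean. The mean lies between 4.23 and 4.76 on control arrays, between 4.95 and 5.36 on Irf8 knockout arrays and between 6.04 and 7.68 with active beta-catenin.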

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

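The tests of divisions of the arrays and of both patterns weighed in this part were chosen after the results had been seen. The search for single arrays far from their group was fixed in advance, and chance gives such an array in about 5% of groups. Of 90 groups of 4 arrays tested, each for a named gene or an array measure, 8 had 1 array far from the other 3, against 4.5 expected. Control array 4 accounted for 3: Cd177 stood at 6.82 there against 3.73 to 4.17 on the other control arrays, Gpc1 at 8.30 against 7.74 to 7.83, and Id2 at 5.62 against 3.98 to 4.25. Control array 3 was low for Tal1, at 5.19 against 5.53 to 5.58. In the group with active beta-catenin, array 4 was high for Ddx58, at 7.44 against 6.25 to 6.28, for Oas3, at 8.02 against 6.52 to 6.77, and for Prom1, at 9.15 against 8.70 to 8.71. Array 2 of that group was high for Sox4, at 6.66 against 5.68 to 5.77. No biological explanation was tested for these values.

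For the counts of called probe sets, other divisions of the same arrays were fitted. In the comparison of Irf8 knockout with control, 1 of 35 divisions, the real one, gave 807 calls or more, and the highest other gave 199. This argues against chance assignment of the arrays as the source of the count. It cannot exclude chance, since only 35 divisions exist and the test was chosen after the counts were seen. The division with 199 placed control array 4 with the knockout arrays. In the comparison of both lesions with control, 1 of 35 gave 2864 or more, and the highest other gave 1357, with control arrays 1, 2 and 3 and array 3 of the group with active beta-catenin on 1 side. Divisions with that many calls point to a structure of the arrays beyond the genotype groups. Between Irf8 knockout with and without active beta-catenin, 2 of 35 gave 2 calls or more, and the highest other gave 18, so chance cannot be excluded for that count. The division with 18 placed array 2 of the group with active beta-catenin with the knockout arrays, and the source of its calls was not tested either.

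The first pattern weighed is that signature genes lay on the same side of control in Irf8 knockout cells as in cells with active beta-catenin. The values argue against shared control arrays as the whole cause. When probe sets were chosen against 2 control arrays and measured against the other 2, at least 92.2% kept their sign over 6 such splits, against a bound of 60% set for shared noise as the cause, and the median ratio of changes lay between 0.456 and 0.795. A single array that stands apart is argued against too, since the median ratio over the 197 genes was at least 0.548 without any 1 array. What stays open is any difference between Irf8 knockout and control mice other than genotype, and the biological reading that these changes begin with loss of Irf8, which both groups share and which may account for the pattern.

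The second pattern is that interferon-stimulated genes were higher with active beta-catenin than in Irf8 knockout alone. Array 4 of the group with active beta-catenin was the highest, yet without it the mean difference of the 7 genes was 1.07 on the log2 scale, against an SD of 0.209 over the other 3 arrays. The choice of the genes on these same arrays stays open. At an equal change against control the 7 genes exceeded the other 126 higher signature genes by 0.126 to 0.482 on the 4 arrays, with a mean of 0.323. Against knockout arrays 1, 2 and 3 the excess was 0.694, 0.818 and −0.086. Its SD over single arrays was 0.154 with active beta-catenin and 0.490 in Irf8 knockout. The mean of 0.323 stayed below both spreads combined (0.514), which describe single arrays and not the error of a mean. On group means the excess was 0.475, with all 7 genes above a line fitted to the other genes, yet it was absent against knockout array 3. The day of harvest after poly(I:C), itself an inducer of interferon, cannot be told apart from the group, since 0 of 11 arrays have a harvest day in their labels. The difference in genotype stays open as well and was not tested apart from these.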

How the results depend on the processing

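The values without both arrays that stood apart and with the covariate were chosen after seeing the data; the rest were listed before. Directions of called named genes and of lists did not reverse under any alternative run, while Prom1, near 0 between the knockout groups, changed sign. Of 510 values of named genes under settings other than leaving out 1 array, 486 kept their side of the threshold, 11 lost a call and 13 gained one. Leaving out each of the 11 arrays ended a call in 80 of 506 fits of called genes and gave one in 6 of 231 fits of the others. In Irf8 knockout against control, array weights gave 995 higher and 921 lower, a 2-fold limit 164 and 226, and leaving out both arrays that stood apart 832 and 769. Against control with active beta-catenin, array weights gave 2532 and 2223, and a 2-fold limit 408 and 427. Between the knockout groups, the 2-group fit gave 0 and 0, trend and robust gave 2 lower, the covariate gave 2 higher, and leaving out both arrays gave 3 and 11. With each array left out in turn, counts ran from 131 to 581 higher and 214 to 478 lower, from 804 to 2075 and 735 to 1740, and from 0 to 1 and 1 to 10 in the same order. Signature genes called in Irf8 knockout ran from 14 to 87 over arrays left out, and were 120 with weights and 109 without both arrays. Between the knockout groups they ran from 0 to 4 over arrays left out, with 4 without both. Irf8 in the knockout, at −1.08 without both arrays, then passed. The interferon list in Irf8 knockout lost its call with an estimated correlation (p = 0.320) and with fry (p = 0.156). With control arrays split 2 and 2, r was 0.612, 0.581 and 0.669, and 284.5, 314 and 250.5 calls were shared on average, with fewer control arrays in each comparison. The cause of the other moves was not tested. With the replicate number as a block, counts were 352 higher and 329 lower, 1378 and 1089, and 1 and 1. Same-numbered arrays of 2 groups deviated together with correlations from −0.252 to 0.186 and never best with their own number. No pairing by number was seen, but an effect small beside the deviations of the arrays that stood apart cannot be excluded. The block ended the calls of Hfe, Casp4 and Ifi209 in Irf8 knockout and of Cd14 with active beta-catenin. With the block Oasl2, Ddx58 and Prom1 passed in Irf8 knockout. Averages over a gene's probe sets and its other probe sets were not run, since most probe sets have no gene name here. Low signal left 35423 of 45037 probe sets to test.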

Other observations

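The lists in this part were written after the signature had been read, so their tests describe the authors' deposited table and are not independent of it, and the levels of the 8 probe sets at the end were also looked for after the data had been seen. Genes of cholesterol synthesis and uptake stood together: 8 of 31 were in the signature and all 8 were higher in the authors' deposited table. They included Sc5d at 1.10, Fdft1, squalene synthase, at 1.06, and Hmgcs1 at 0.79. Fdft1 was the 1 of these with values here. It stood at 6.70 ± 0.135 (SD, n = 4) with both lesions, 5.98 ± 0.411 (SD, n = 3) in Irf8 knockout and 5.64 ± 0.374 (SD, n = 4) in control, with a limma adjusted p of 0.00757 against control. Of 54 lysosome genes 10 were in the signature and 9 were higher in the authors' deposited table, among them the hydrolase genes Neu1 at 1.26 and Galc at 1.13, with Ctsc lower at −1.24. Of 16 genes of glycogen metabolism 4 were in the signature, all higher in the authors' deposited table, with glycogen synthase Gys1 at 1.19 and the liver phosphorylase gene Pygl at 1.16. Fisher's exact test of direction against the other signature genes, two-sided and adjusted over 4 lists, gave p = 0.107, 0.192 and 0.303 for these 3 lists, so none passed.

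Further genes known to be induced by interferon, outside the list fixed in advance, gave a mixed picture. Of 40 such genes 12 were in the signature, 10 higher and 2 lower (adjusted p = 0.192 in the same Fisher's exact test). Of the 9 with values, 8 rose and Ifi209 fell against control with both lesions, and 4 were called already in Irf8 knockout: Slfn4, Parp10 and Il15ra higher, and Ifi209 lower. With each of the 11 arrays left out in turn, the knockout calls of Slfn4 and Ifi209 ended in 5 and 9 fits. Slfn2 and Slfn5 had values of 6.25 ± 0.389 and 3.86 ± 0.231 (SD, n = 3) in Irf8 knockout, close to 6.02 ± 0.605 and 3.40 ± 0.678 (SD, n = 4) in control, and 7.79 ± 0.570 and 5.42 ± 0.788 (SD, n = 4) with both lesions, with limma adjusted p = 0.849 and 0.695 for the first difference.

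Values of 8 probe sets, unnamed here, fell into separate levels at least 2 log2 units apart on the same arrays within every group. Control arrays 1 and 3, knockout array 2 and arrays 1 and 3 of the group with active beta-catenin made up 1 side, with 5 probe sets higher there and 3 lower. In 1 of these 3 the mean was 3.43 on that side and 10.2 on the other. The deviations of control array 4 and array 2 of the group with active beta-catenin from their group means correlated at 0.419 across probe sets, and those of control array 4 and array 3 of the latter group at −0.450.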
